A study of Mus musculus with 32 samples.

How the data were processed

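Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in CD8+ T cells of OT-I mice, whose T cell receptor recognises an ovalbumin peptide. The cells were cultured with splenocytes loaded with the ovalbumin peptide SIINFEKL (N4), a strong agonist, or with its altered form SIITFEKL (T4), with or without PRN-694, an inhibitor of the kinases ITK and RLK (RLK is encoded by Txk). The labels give 50 nM PRN-694, added 30 min before stimulation, and loading of the splenocytes with peptide for 60 min. They give no peptide concentration. Libraries came from 50000 sorted cells each (CD45.2+ CD8a+, apart from the CD45.1+ presenting cells), a transposition of 60 min and fragments of up to 450 bp. The 32 libraries form 16 groups of 2: unstimulated cells at 0, 30, 60 and 120 min, and N4, T4, N4 with PRN-694 and T4 with PRN-694 at 30, 60 and 120 min. The labels do not say whether the libraries of a group came from separate animals. Coverage of chromosome Y, listed at 0 in replicate 1 and present in replicate 2, shows that the 2 libraries of each group came from different mice. Whether libraries of 1 replicate number shared mice is not known, so the p-values of comparisons between groups measure only the spread between these samples. The labels also give the mice as lacking Rag1 in one place and Rag2 in another.

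The authors deposited 1 table of 95717 ATAC regions and a matching list of positions in mm10. The unit of the deposited values is a signal, the mean per-base coverage of each region in each library, not scaled by depth. Among values from 1 to 10, 96.3% multiplied by the region's length gave a whole number within 0.02 bases. Covered bases under 300 per region fell on multiples of 29 bases in 47.0% of cases, against 1.79% for multiples of 30 bases, so each mapped end seems to have been counted over 29 bases. The submitters' processing notes name cutadapt 1.3, Bowtie2 2.1.0, Picard, SAMtools 1.4.1, bedtools 2.26.0, MACS2 2.1.1 and DESeq2 1.26.0 without role or order. The values are not read counts, so the edgeR test planned for counts and the DESeq2 alternative were not run, and limma on logged values, set out for that case, took their place.

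Coverage was multiplied by region length, summed to 175 to 546 megabases per library, scaled between libraries by trimmed mean of M values (trims 0.3 and 0.05; factors 0.937 to 1.06) and returned to mean coverage per base. Regions with a scaled coverage of at least 1 in at least 2 libraries were kept, which left 95623 and removed 94. The median region was 283 bp long (201 to 4716 bp) and had a median scaled coverage of 4.23. Each test used limma 3.58.1 in R 4.3.3 on log2(scaled coverage + 1), with all 32 libraries in 1 fit, 1 mean per group, a trend of the variance with level and robust moderation. This gave 16 residual and 13.5 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all regions of a comparison, and a region was called at an adjusted p under 0.05. The added value of 1 pulls the fold changes of weakly covered regions toward 0. Errors of fold changes are limma's moderated standard errors, and levels are means ± SD of 2 libraries.

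Positions count from 1 in mm10. A region was given the nearest protein-coding gene of the reference annotation (GRCm38.p6) when its span lay within 50 kb, which held for 87332 regions. The annotation carried no strand, so regions within 1 kb of either end of a gene stood in for promoters. No genome sequence was at hand, so the planned motif test was not run. Gene lists fixed before the data were examined covered activation transcription factors, cytokines and chemokines, the NF-kB pathway, MAPK feedback, activation receptors, naive and quiescence genes, cytotoxic effector genes, T cell receptor signalling components, growth and metabolism, housekeeping genes, and markers of B cells, myeloid and dendritic cells, CD4 T cells, NK cells and erythroid cells. These 15 lists were tested with camera (limma) against all other regions with a preset correlation of 0.01 and adjusted over 405 pairs of list and comparison. Camera called 94 pairs. None of the 94 calls held with an estimated correlation (lowest adjusted p = 0.172). Of the genes on the CD4 T cell list 5 of 12, and on the NK cell list 7 of 15, also stand on another list.

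Design, alternatives, lists and the rule for named regions were set before the data were examined. The rule took, for N4 and T4 against unstimulated cells, N4 against T4 and the inhibitor under each peptide, at each time, up to 5 called regions in each direction with the largest change, a mean coverage of at least 2 and no overlap between the groups. It took also up to 4 genes per list with the smallest p under N4 at the time with the most calls, and the regions of Itk and Txk as values. In all 1898 calls of named regions, Itk and Txk included, both libraries of a group lay on the same side of both libraries of the other. Chance alone puts 33.3% of unselected regions in such an order. A call by itself favours that order, and part of the rule required it, so the order is no separate support for the calls.

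The size of the response was also measured with regions ranked by N4 against unstimulated cells in the libraries of 1 replicate number (the top 1000) and the log2 ratio of every condition read in the libraries of the other number, and the other way round. The shares of regions near gene ends were compared by two-sided Fisher's exact tests. These take regions as independent units, also where several belong to 1 gene, and hold no spread between samples.

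The labels number the libraries of every group 1 and 2. The log2 differences between the numbers correlated between all 120 pairs of groups (r = 0.147 to 0.407 across regions, median 0.263), so the numbers were taken as a pairing of samples. Counts and p-values are nevertheless those of the fit without the block unless the block is named. That fit leaves the difference between the numbers in the spread. The fit with the number as a block is given where it changes a call or a count by over 1.5 times. The effect of the block on the counts had been seen by then. Alternatives fixed beforehand were median-of-ratios scaling, scaling by total coverage, no filter, an added value of 0.1, the replicate block and leaving out each library in turn. Leaving out a library leaves a lone library, assumed to vary like the other groups. Those fits held no block, so the lone library also sets 1 replicate number against groups with both. Quantile normalization and the block with an estimated correlation were added after the data were seen. The procedure was tested on counts drawn at random around the mean level of each region at the depth of each library. These held no other response to stimulation and no difference between replicate numbers, so errors from such a difference were not covered. Changes of 1.5, 2 and 4 times were placed in 1 group, in 67, 67 and 66 of 95257 regions. They were called in 5.97%, 23.9% and 74.2% of cases, with 0 called in the wrong direction. The adjustment of p depends on how many regions change, so these shares do not give the power of comparisons with many more changed regions. There were 2 calls among unchanged regions and 0 calls over 12 comparisons without a change. The share of changes of 4 times missed the bar first set for it, and criteria of correctness replaced that bar. Tables were read with data.table (version 1.17.8), and plots drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.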

Results

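The accessibility of 95717 regions was recorded in 32 libraries of OT-I CD8+ T cells, in 16 groups of 2. Unstimulated cells were taken at 0, 30, 60 and 120 min. Cells stimulated with N4, a strong agonist peptide, or with T4, an altered peptide, were taken at 30, 60 and 120 min, with or without PRN-694, which inhibits the T cell kinases ITK and RLK. The study asked how ITK activity shapes gene induction by stimuli of different strength. Accessibility was compared over time in culture, between each stimulated group and unstimulated cells of the same time, between the peptides, and between cells with and without the inhibitor.

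Depth differed between libraries. Coverage summed over all regions ran from 175 megabases in N4 with PRN-694 at 120 min (replicate 1) to 546 megabases in unstimulated cells at 30 min (replicate 1). Unstimulated libraries held 343 to 546 covered megabases, N4 libraries 331 to 437, T4 libraries 291 to 425, libraries of N4 with PRN-694 175 to 408, and of T4 with PRN-694 316 to 455. Mitochondrial regions took 6.7 to 12.4% of the coverage. Replicates correlated at r = 0.949 to 0.973 across regions, which are not independent replicates. Their spread was 2.78 to 7.43 times the variance that counting alone would give (chi-square per degree of freedom). The first principal component held 56.9% of the variance, the second 8.57% and the third 5.68%, and the third parted the replicate numbers in all 16 groups.

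**Figure D1:**
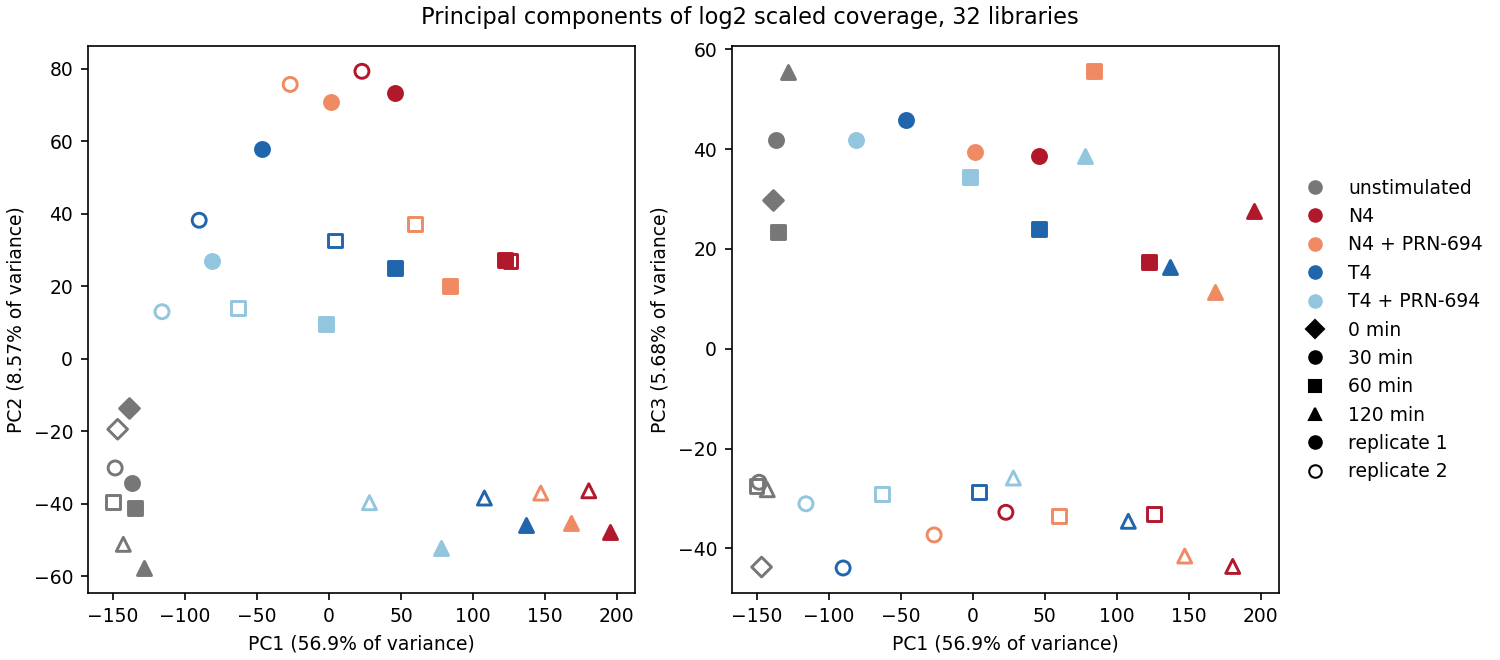
Principal components of log2 scaled coverage in 32 libraries (each point a library; colour, stimulus; shape, time; filled, replicate 1; open, replicate 2). Stimulation and time spread the libraries along the first component (56.9% of the variance), and the third (5.68%) parted the replicate numbers.

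Unstimulated cells were compared with cells at 0 min to see what culture alone changed. At 120 min, 171 regions were higher and 251 lower than at 0 min, and at 60 min 5 were higher and 37 lower. At 30 min limma called 0 regions, with 4076 at an unadjusted p under 0.05. That is below the share of 0.05 of the 95623 regions that chance alone would put there. The 5 higher at 60 min, listed after their values were seen, lay inside Plec, which encodes a cytoskeletal linker (log2 1.16), Kctd5, a ubiquitin ligase adaptor (adjusted p = 0.0444), Myo1f, an immune cell myosin (1.10), and Add1, a membrane skeleton protein (1.05), and 48234 bp outside Mturn, a differentiation regulator (1.42, adjusted p = 0.0142). A region 2575 bp outside the gene Dusp5 (mm10 chromosome 19, 53544384 to 53544726), which encodes a phosphatase that dampens ERK, was lower at 120 min, with a log2 change of -0.97 (SE 0.191, adjusted p = 0.0134). Its call ended without either library of 0 min (replicate 1 0.0985, replicate 2 0.124) or of 120 min (replicate 1 0.0727, replicate 2 0.178). The regions of the immediate early genes Egr1 (log2 0.02) and Nr4a1 (-0.20) and of the naive genes Tcf7 (-0.07) and Lef1 (0.07) were not called at 120 min. None of the 15 gene lists was called at any time. The counts moved with single libraries and with the replicate number. With the number as a block they were 86, 772 and 3105 at 30, 60 and 120 min. At 30 min the count was 1 without the 0 min replicate 2. At 60 min it was 2 and 7 without replicates 1 and 2 of 0 min, and 0 and 5 without replicates 1 and 2 of 60 min. At 120 min it was 150 (114 higher and 36 lower) and 132 without replicates 1 and 2 of 0 min, and 36 and 106 (56 higher and 50 lower) without replicates 1 and 2 of 120 min. The split at 120 min was 244 higher and 211 lower under median-of-ratios scaling, and 253 and 216 under total scaling. With the block it was 1744 higher and 1361 lower, and 435 and 337 at 60 min.

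N4 was compared with unstimulated cells of the same time to find what a strong stimulus opened and closed. Regions at the immediate early genes Egr1, Egr3 and Nr4a1 opened most at 30 min, by log2 values above 5, from levels near 0. Regions in Zap70, Exoc2 and Il2ra opened more with time and were highest at 120 min. Regions at the naive genes Tcf7, Lef1 and S1pr1 and at Cd28 closed steadily. In all, 11214 regions were higher and 11837 lower at 30 min, 19612 and 15413 at 60 min, and 23570 and 18195 at 120 min. Which side was larger hung on the setting: at 30 min it was 12185 higher and 11089 lower under total scaling, 11130 and 10884 with an added value of 0.1 and 14377 and 14358 with the replicate block, 8483 and 7976 without unstimulated replicate 1 and 9109 and 7888 without N4 replicate 2, and under quantile normalization 16382 and 17095 at 60 min and 19938 and 21515 at 120 min. The median log2 change of the higher regions grew from 1.16 at 30 min to 1.43 at 120 min, and that of the lower regions was -1.06, -1.06 and -1.09.

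Among activation transcription factors, Egr1 encodes a zinc finger factor induced by ERK. A region at its end (mm10 chromosome 18, 34864695 to 34866115) had a coverage of 0.441 ± 0.202 (SD, n = 2) in unstimulated cells and 47.6 ± 1.78 with N4 at 30 min, a log2 change of 5.08 (SE 0.307, adjusted p = 4.23e-12) that declined to 4.32 at 60 min and 3.35 at 120 min. Its relative Egr3 had a region 3225 bp outside the gene (chromosome 14, 70085838 to 70086260) that rose by 5.21 (SE 0.299, adjusted p = 1.71e-12) at 30 min, and by 1.41 at 120 min. Egr2, which restrains T cell activation, rose by 4.36, 3.83 and 3.57 at 30, 60 and 120 min at a region by its end (chromosome 10, 67542256 to 67542566). Nr4a1 encodes the orphan receptor Nur77, a reporter of receptor signalling. A region 236 bp outside the gene (chromosome 15, 101275031 to 101276794) rose by 5.07 (SE 0.296, adjusted p = 3.11e-12), 4.72 and 4.30. Atf3, a stress-response factor, rose by 1.91 at 30 min and 3.98 at 120 min, and Tox2, a factor linked to T cell differentiation, by 1.73 and 3.28. Of 40 genes on this list, 33 had a higher and 17 a lower region at 30 min. The list had 186 higher and 34 lower of 546 regions at 30 min (202 and 39 adjusted over the list alone; camera adjusted p = 5.94e-08, adjusted p = 0.483 with an estimated correlation), 238 higher and 45 lower at 60 min (1.00e-06) and 262 higher and 63 lower at 120 min (1.16e-05).

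Among NF-kB genes, Rel encodes the subunit c-Rel, and a region inside it (chromosome 11, 23754294 to 23754621) rose by 3.60 (SE 0.287, adjusted p = 5.36e-10), 4.51 and 4.29 at 30, 60 and 120 min. Nfkb1, which encodes the p105 precursor, rose by 1.95, 4.62 and 4.56 at a region inside the gene (chromosome 3, 135635709 to 135635970). A region 13297 bp outside the gene of Tnfaip3, which encodes the NF-kB inhibitor A20, rose by 2.48 at 60 min and 3.54 at 120 min. A region 43518 bp outside the gene of Card11, a scaffold upstream of NF-kB, changed by -1.11 to -1.84. This list had 147 higher and 67 lower of 382 regions at 120 min (155 and 68 adjusted over the list alone; camera adjusted p = 0.0274, adjusted p = 0.793 with an estimated correlation), after 112 higher and 36 lower at 30 min (8.24e-04) and 148 higher and 58 lower at 60 min (0.00882).

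Among cytokine and chemokine genes, Tnfsf9 encodes the ligand of the receptor 4-1BB, and a region 1088 bp outside the gene (chromosome 17, 57108846 to 57109111) rose by 2.78, 3.60 and 4.21 (SE 0.208, adjusted p = 1.21e-14 at 120 min). Ccl4, an inflammatory chemokine, rose by 2.47, 3.59 and 3.88, and Ccl1, a T cell chemokine, by 1.21, 2.55 and 3.45. A region 22484 bp outside the gene of Cd40lg, the ligand of CD40, changed by -2.23, -2.72 and -3.16. The list had 136 higher and 30 lower of 252 regions at 120 min (136 and 32 adjusted over the list alone; camera adjusted p = 1.16e-05, adjusted p = 0.554 with an estimated correlation), after 77 higher and 19 lower at 30 min and 117 higher and 25 lower at 60 min.

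Among growth genes, Slc7a5 and Slc3a2 encode the chains of an amino acid transporter. A region inside Slc7a5 (chromosome 8, 121898556 to 121898826) rose by 1.94, 2.74 and 4.32 (SE 0.25), and a region 5203 bp outside the gene of Slc3a2 by 2.14, 3.56 and 4.42. Pfkfb3, a regulator of glycolysis, rose by 1.59, 3.27 and 4.67. The growth list had 177 higher and 49 lower of 389 regions at 120 min (182 and 51 adjusted over the list alone; camera adjusted p = 1.36e-04, adjusted p = 0.172 with an estimated correlation) and 72 higher and 30 lower at 30 min (0.0212). The MAPK feedback genes Dusp5 and Spry1, both dampers of ERK, rose by 3.69 (SE 0.191) and 3.78 (SE 0.276) at 120 min. Their list had 117 higher and 47 lower of 333 regions (118 and 48 adjusted over the list alone; camera adjusted p = 0.0575, 0.0366 with the replicate block), and was called at 60 min (0.0425; 0.549 with an estimated correlation; 0.239 with regions within 10 kb).

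Receptor genes moved both ways. Il2ra encodes the alpha chain of the interleukin 2 receptor. A region inside it (chromosome 2, 11691275 to 11691534) was listed at 0 in both unstimulated libraries at 30 min, was not called at 30 min, and rose by 2.04 at 60 min and 4.19 at 120 min (SE 0.399, adjusted p = 1.12e-09). Tnfrsf1b, a receptor for tumour necrosis factor, rose by 3.44, 4.01 and 4.19, and Il21r, the interleukin 21 receptor, by 2.47, 3.73 and 3.41. The costimulatory receptor gene Cd28 changed by -1.44, -2.65 and -3.17 (SE 0.159) at a region inside it (chromosome 1, 60758256 to 60758570). The receptor list had 201 higher and 104 lower of 479 regions at 120 min (206 and 110 adjusted over the list alone; camera adjusted p = 0.0608, 0.0294 with the replicate block), and at 60 min 0.0546 (0.0238 with the block). Among cytotoxic effector genes, Gzmb, which encodes granzyme B, rose by 1.81 to 3.15, Srgn, the granule proteoglycan, by 3.56 to 3.44, and Klrk1, the receptor NKG2D, changed by -1.28 to -2.53. That list had 69 higher and 30 lower of 194 regions (72 and 34 adjusted over the list alone; camera adjusted p = 0.152).

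Naive and quiescence genes had more lower than higher regions. Their regions had a median scaled coverage of 8.14 in unstimulated cells at 0 min, against 4.00 over all regions and 2.95 for cytokine regions. Camera did not match regions by level, so the part that level plays in the direction of a list was not tested. Tcf7 encodes TCF1, a factor of naive and memory cells, and a region inside it (chromosome 11, 52268491 to 52268814) fell from 73.2 ± 4.4 in unstimulated cells to 9.26 ± 1.25 with N4 at 120 min. Its log2 changes were -1.80 (SE 0.157, adjusted p = 2.22e-09), -2.63 and -2.86. Lef1, a relative of TCF1, changed by -1.77, -2.15 and -2.38 (SE 0.138) at a region inside the gene (chromosome 3, 131157481 to 131157741). S1pr1, which lets T cells leave lymphoid organs, changed by -1.18, -2.05 and -2.47, and Slfn2, a quiescence gene, by -1.08, -1.94 and -2.59. The list had 116 higher and 268 lower of 890 regions at 30 min (136 and 296 adjusted over the list alone; camera adjusted p = 4.57e-04, adjusted p = 0.483 with an estimated correlation), 186 higher and 327 lower at 60 min (0.00206) and 230 higher and 319 lower at 120 min (0.0277). The largest losses at 30 min lay in Eps15l1, an endocytosis adaptor (-3.76; chromosome 8, 72351638 to 72351870), and Rnf138, a ubiquitin ligase (-3.62), the largest at 60 min by Usp28, a deubiquitinase (-4.13), and the largest at 120 min in St8sia6, a sialyltransferase (-3.98).

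T cell receptor signalling components moved in both directions. A region inside Zap70, the kinase bound to the activated receptor (chromosome 1, 36768899 to 36769138), rose by 3.74, 4.58 and 5.33 (SE 0.353, adjusted p = 8.13e-12), and a region inside Exoc2, a subunit gene of the exocyst that tethers vesicles, by 2.27, 3.90 and 5.23. A region inside Fyn, a Src family kinase, rose by 2.85, 3.74 and 4.72. Stim1, a sensor of stored calcium, changed by -1.28, -2.12 and -2.42, and Grap2, an adaptor, by -1.10, -1.61 and -2.35. The list had 365 higher and 305 lower of 1120 regions at 120 min (377 and 322 adjusted over the list alone; camera adjusted p = 0.935); its median log2 change was 0.04 and its mean 0.22, while the test pointed down. The housekeeping list had 31 higher and 22 lower of 139 regions (31 and 22 adjusted over the list alone; camera adjusted p = 0.753). Of the marker lists of other cell types, B cell markers had 21 higher and 12 lower of 79 regions at 120 min (camera adjusted p = 0.554), with H2-Aa, an MHC class II gene, higher by 3.53 and Cd79a, a B cell receptor chain, lower (log2 -2.73). Myeloid and dendritic markers had 30 higher and 34 lower of 130 regions (adjusted p = 0.562; median 0.05, test down), CD4 T cell markers 47 higher and 36 lower of 141 regions (0.979), NK cell markers 25 higher and 26 lower of 108 regions (0.534) and erythroid markers 6 higher and 2 lower of 29 regions (0.727). Over these marker lists, 20 and 12 adjusted over the list alone were called for B cells, 31 and 35 for myeloid cells, 49 and 39 for CD4 T cells, 25 and 26 for NK cells, and 6 and 2 for erythroid cells.

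These values came from limma, with 2 libraries per group. Every N4 region named here, apart from those said not to be called, lay on the same side in both libraries of each group and kept its call without any single library.

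**Figure D2:**
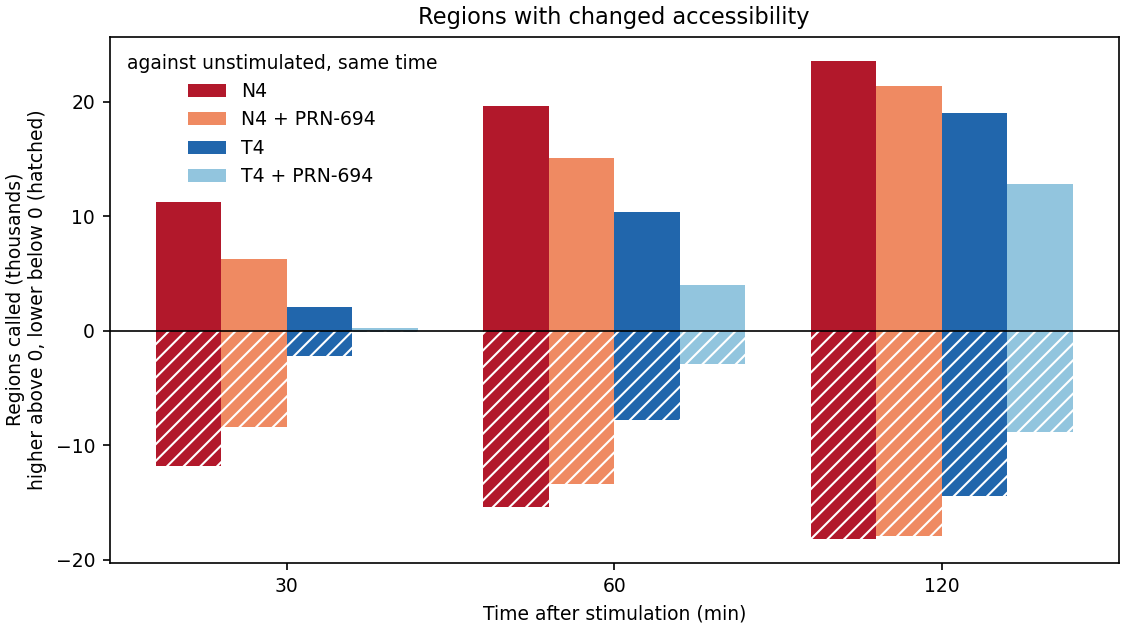
Regions called (y axis, in units of 1000) higher (above 0) and lower (hatched, below 0) than in unstimulated cells at 30, 60 and 120 min, for N4, N4 with PRN-694, T4 and T4 with PRN-694. N4 called 23051 regions at 30 min and T4 with PRN-694 called 336.

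T4 was compared with unstimulated cells to find what an altered peptide opened. The immediate early genes responded to T4 by nearly as much as to N4: Egr1 rose by 4.89 at 30 min (SE 0.307, adjusted p = 1.24e-11; coverage 43.1 ± 16.7), Nr4a1 by 4.85, Egr3 by 5.10 and Egr2 by 4.10. Zap70 rose by 2.29, 3.71 and 4.73 at 30, 60 and 120 min, and Rel by 2.13, 3.97 and 4.00. Exoc2 (chromosome 13, 30831355 to 30831637) was not called at 30 min (log2 0.66) and rose by 2.88 and 4.91. In all, 2064 regions were higher and 2188 lower at 30 min, 10368 and 7829 at 60 min, and 18991 and 14468 at 120 min, with median log2 changes of 1.19, 1.17 and 1.25 in the higher and -0.98, -0.96 and -1.04 in the lower regions. The count at 30 min was 566 without T4 replicate 1, 1627 without unstimulated replicate 1 and 1224 without unstimulated replicate 2, and 8847 with the replicate block. The split at 30 min turned to 2354 higher and 1606 lower with an added value of 0.1 and to 1867 and 1664 under quantile normalization, to 381 and 185 without T4 replicate 1, 2688 and 1852 without T4 replicate 2, and 1237 and 390 or 713 and 511 without unstimulated replicates 1 or 2, and that at 120 min to 15911 and 16842 under quantile normalization. At 60 min the count was 9019 without T4 replicate 1 and 10226 without unstimulated replicate 2.

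Cytokine regions at Tnfsf9 rose by 1.67, 2.86 and 3.39 with T4, and at Ccl4 by 1.96 at 30 min and 3.33 at 120 min. Among receptors, Tnfrsf1b rose by 2.67 to 3.89, Il21r by 1.48 to 3.15, and Il2ra by 3.77 at 120 min (adjusted p = 2.05e-08), while at 60 min Il2ra was called only with the replicate block (log2 1.04, adjusted p = 0.067, 0.0108 with the block). Tagap, a T cell GTPase-activating protein, rose by 3.34, 3.31 and 3.23 at a region 785 bp outside the gene (chromosome 17, 7935682 to 7936518). The growth genes Slc3a2 and Pfkfb3 rose by 2.20 and 2.47 at 60 min and by 4.03 and 3.98 at 120 min, and Slc7a5 by 3.68 at 120 min. The feedback gene Dusp5 rose by 2.28, 2.49 and 3.66, and Spry1 by 1.84 and 2.38. Gzmb rose by 2.01 and 2.76. Among naive genes, Lef1 changed by -0.74, -1.16 and -1.67, Tcf7 by -1.33 and -2.11, S1pr1 by -0.90 and -1.90, and Cd28 by -1.25 and -2.39. Rnf138 changed by -1.86 and Klhl6, an adaptor for protein degradation in lymphocytes, by -1.42 at 30 min.

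With T4, activation transcription factors had 85 higher and 4 lower of 546 regions at 30 min (111 and 11 adjusted over the list alone; camera adjusted p = 2.76e-10, adjusted p = 0.387 with an estimated correlation) and 239 higher and 40 lower at 120 min. Cytokines had 20 higher and 5 lower at 30 min (26 and 7 adjusted over the list alone; 0.00955; 0.826 with an estimated correlation) and 116 higher and 24 lower at 120 min (1.65e-05). The NF-kB list had 28 higher and 4 lower at 30 min (35 and 8 adjusted over the list alone; 0.00211) and 135 higher and 46 lower at 120 min (0.00811). Naive genes had 27 higher and 77 lower of 890 regions at 30 min (38 and 130 adjusted over the list alone; camera adjusted p = 1.73e-04, adjusted p = 0.483 with an estimated correlation) and 180 higher and 297 lower at 120 min (0.00594). Activation receptors had 178 higher and 86 lower (camera adjusted p = 0.0374) and growth genes 152 higher and 34 lower at 120 min (6.69e-05). Neither of these calls held with an estimated correlation. The housekeeping list was called with T4 at 30 min, with 8 higher and 3 lower of 139 regions (camera adjusted p = 0.0428, adjusted p = 0.483 with an estimated correlation).

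N4 was compared with T4 directly, to find what peptide strength changed at a given time. N4 opened the regions at Tnfsf9 and Rel more than T4 at 30 min, and closed those at Tcf7, Lef1, S1pr1, Slfn2 and Cd28 further. Egr1 (log2 0.19, -0.57 and -0.02) and Nr4a1 (0.22, -0.11 and 0.20) were not called at any time. In all, 2308 regions were higher and 2106 lower with N4 at 30 min, 1766 and 1731 at 60 min, and 268 and 187 at 120 min.

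At 30 min the region at Tnfsf9 was higher with N4 by 1.11 (SE 0.208, adjusted p = 0.0024), and regions by Mex3c, an RNA-binding ubiquitin ligase (2.11; chromosome 18, 73576001 to 73576258), Hspa4, a chaperone (2.15), H2-Aa (2.02) and Adgrg1, an adhesion receptor of cytotoxic cells (1.52), were higher as well. The Rel region reached 20.4 ± 0.425 with N4 and 7.2 ± 3.76 with T4, a difference of 1.47 (SE 0.287, adjusted p = 0.00342) whose call ended without T4 replicate 2 (0.157). Lower with N4 were regions in Tcf7, with log2 differences of -1.13 at 30 min (adjusted p = 2.23e-04) and -1.30 at 60 min, in Lef1 with -1.03 and -0.99, in Cd28 with -1.40 at 60 min (adjusted p = 5.72e-04 at 30 min and 4.36e-05 at 60 min), and near S1pr1 with -0.87 and -1.15. The region near Slfn2 (chromosome 11, 83079847 to 83080117) was lower at all 3 times, with differences of -0.88, -1.21 and -1.11 (SE 0.159, adjusted p = 0.00113 at 120 min). Regions in Wwox, an oxidoreductase (-2.10, adjusted p = 2.73e-06; chromosome 8, 114973073 to 114973381), Jak1, a cytokine receptor kinase (-2.03; chromosome 4, 101185303 to 101185557), Klhl6 (-1.91), Rnf138 (-1.75), Eps15l1 (-2.33) and Srgap1, a regulator of Rho GTPases (-1.51), were lower with N4 at 30 min. At 60 min Stim1 (-1.23), Gramd3, a lipid-binding protein gene (-1.82), Tmsb10, a thymosin that binds actin (-1.87), and a region 6738 bp outside the gene of Itk (-1.11) were lower. At 120 min Fcgr3, an Fc receptor (-1.39), Sptbn1, a spectrin (-1.32), and Dgka, a diacylglycerol kinase that damps Ras signalling (-0.79), were lower.

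Camera called cytokine genes, toward higher values with N4, at 30 min, with 16 higher and 6 lower of 252 regions (23 and 8 adjusted over the list alone; camera adjusted p = 0.00178, adjusted p = 0.793 with an estimated correlation), at 60 min (7 higher and 4 lower; 0.0181) and at 120 min, with 0 regions called by limma (6 and 2 adjusted over the list alone; camera adjusted p = 0.0143). With regions within 10 kb the cytokine calls ended at 60 min (0.0822) and 120 min (0.106). Activation transcription factors had 29 higher and 7 lower of 546 regions (41 and 7 adjusted over the list alone; 0.0111; 0.793 with an estimated correlation) and the NF-kB list 29 higher and 10 lower at 30 min (39 and 10 adjusted over the list alone; 0.0247). Naive genes were called as a list toward lower values with N4 at 30 min (28 higher and 72 lower of 890 regions, 47 and 99 adjusted over the list alone, camera adjusted p = 0.0426, 0.0502 with the block). They were also called at 60 min (10 higher and 51 lower, camera adjusted p = 0.0355). Neither call held with an estimated correlation. Growth genes were called as a list toward higher values at 60 min (15 higher and 3 lower of 389 regions, camera adjusted p = 0.0111). This call also ended with an estimated correlation. Receptors were called at 30 min with the block (0.0873; 0.0487 with the block).

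The counts of N4 against T4 moved with single libraries. At 30 min limma called 998 regions without N4 replicate 1 (197 higher and 801 lower), 1438 without N4 replicate 2 and 546 without T4 replicate 2 (194 and 352). The 60 min count was 1059 without N4 replicate 1 (404 and 655), 427 without N4 replicate 2 (119 and 308) and 202 without T4 replicate 2 (63 and 139). At 120 min it called 61 (5 and 56) and 57 without N4 replicates 1 and 2, and 114 (44 and 70) and 27 without T4 replicates 1 and 2, so which side was larger is not settled at any time. With the block the counts were 9966, 8377 and 2054. Total scaling gave 3223 higher and 1489 lower at 30 min. With an added value of 0.1 the splits were 1717 higher and 1894 lower at 30 min, 245 and 1423 at 60 min and 3 and 165 at 120 min, and quantile normalization gave 1822 and 2315 at 60 min and 396 and 442 at 120 min.

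Cells given PRN-694 with N4 or T4 were compared with unstimulated cells to see what response the inhibitor left. With N4 and the inhibitor, Egr1 rose by 4.97 and Nr4a1 by 5.07 at 30 min. Zap70 rose by 5.09, Rel by 4.30, Il2ra by 3.87, Slc7a5 by 4.14 and Tnfsf9 by 3.97 at 120 min, while Tcf7 changed by -2.79, Lef1 by -2.21 and Cd28 by -3.24. With T4 and the inhibitor, Egr1 rose by 4.35 (adjusted p = 3.32e-10), Nr4a1 by 4.26, Egr3 by 4.42, Egr2 by 2.96 and Dusp5 by 1.93 at 30 min. Zap70 was not called at 30 min (log2 0.85) and rose by 2.46 at 60 min and 3.53 at 120 min, Rel by 2.55 and 2.92, Slc3a2 by 1.97 and 3.46, and Tnfsf9 by 1.95 at 60 min. Tcf7 changed by -1.20 and -1.88 and Lef1 by -0.76 and -1.16, and at 30 min both were called with the block alone (adjusted p = 0.13 and 0.193, 0.0198 and 0.0376 with the block). The Spry1 region at 37674980 on chromosome 3 was not called at 120 min (log2 0.54, adjusted p = 0.17), while a second Spry1 region (chromosome 3, 37672375 to 37672627) rose by 1.33 (adjusted p = 0.00121).

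With N4 and the inhibitor, 6266 regions were higher and 8378 lower at 30 min, 15069 and 13379 at 60 min, and 21342 and 17920 at 120 min. Quantile normalization turned the last 2 to 12779 and 12876, and 18505 and 19657. With T4 and the inhibitor, 239 were higher and 97 lower at 30 min, 3990 and 2932 at 60 min, and 12800 and 8848 at 120 min. For N4 with the inhibitor the count at 30 min was 8901 and 8726 without its replicate 1 or unstimulated replicate 2, and 9369 without unstimulated replicate 1. At 60 min it was 18473 without its replicate 1. For T4 with the inhibitor the count at 30 min was 30 without its replicate 1, 142 without unstimulated replicate 1, 58 without unstimulated replicate 2, and 2030 with the block. At 60 min it was 1006 without its replicate 1, 3607 and 2372 without unstimulated replicates 1 and 2, and 12409 with the block, and at 120 min 10495 without its replicate 1. Median-of-ratios scaling gave 201 higher and 139 lower at 30 min, and total scaling 5169 and 1920 at 60 min. Activation transcription factors had 253 higher and 63 lower of 546 regions with N4 and the inhibitor at 120 min (257 and 70 adjusted over the list alone; camera adjusted p = 1.25e-05, adjusted p = 0.51 with an estimated correlation). With T4 and the inhibitor that list had 36 higher and 0 lower at 30 min (57 and 3 adjusted over the list alone; camera adjusted p = 1.00e-06, adjusted p = 0.483 with an estimated correlation) and 174 higher and 22 lower at 120 min. Naive genes had 4 higher and 12 lower of 890 regions at 30 min (14 and 62 adjusted over the list alone; camera adjusted p = 4.44e-08, adjusted p = 0.228 with an estimated correlation) and 121 higher and 229 lower at 120 min.

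**Figure D3:**
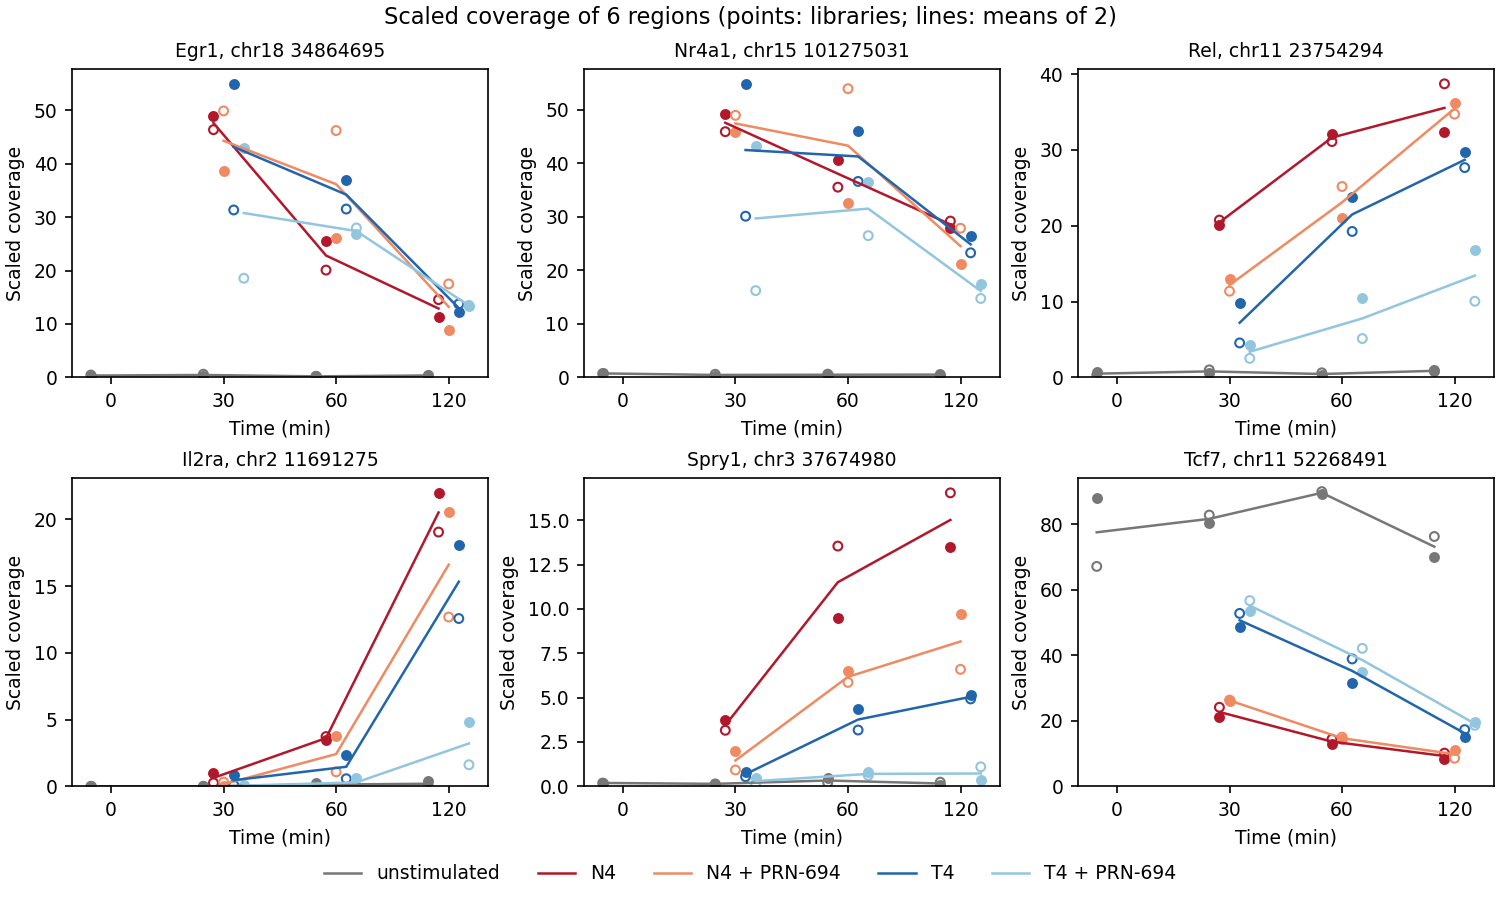
Scaled coverage per base (y axis) at 0, 30, 60 and 120 min at Egr1, Nr4a1, Rel, Il2ra, Spry1 and Tcf7, chosen for the plot after their values were seen (lines, means of 2 libraries; filled points, replicate 1; open, replicate 2). At 120 min Spry1 reached 15.0 ± 2.16 (SD) with N4, 5.05 ± 0.17 with T4 and 0.724 ± 0.531 with T4 and PRN-694.

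Under T4, cells with the inhibitor were compared with cells without it, to find what ITK and RLK inhibition changed under the altered peptide. At 120 min the inhibitor lowered regions at the feedback genes Spry1 and Dusp5, the receptor genes Il2ra and Tnfrsf1b, the cytokine genes Tnfsf9 and Ccl4 and the amino acid transporter gene Slc7a1. It raised regions in Bcl2, a survival gene, in Cd28 and in Grap2. In all, 340 regions were higher and 486 lower with the inhibitor at 120 min. At 30 min 2 were lower. At 60 min limma called 0 regions, with 7215 at an unadjusted p under 0.05 (2 with total scaling, 6 with quantile normalization, 677 with the block).

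At 120 min the Spry1 region (chromosome 3, 37674980 to 37675640) fell from 5.05 ± 0.17 (SD, n = 2) with T4 to 0.724 ± 0.531 with the inhibitor, a log2 change of -1.85 (SE 0.276, adjusted p = 0.003). The Il2ra region went from 15.3 ± 3.9 to 3.21 (4.81 and 1.61 in the libraries), a change of -2.05 (SE 0.399, adjusted p = 0.0139). Regions near Dusp22, a phosphatase (-1.83; chromosome 13, 30637590 to 30637989), Furin, a protease that matures cytokines (-1.78), and Ankrd46 (-1.45) also fell. So did Slc7a1 (-1.51), Exoc2 (-1.48), Lclat1, a lipid acyltransferase (-1.41), Fyn (-1.26), Ccl4 (-1.21), Tnfsf9 (-1.13, adjusted p = 0.00971), Dusp5 (-1.12, adjusted p = 0.00633) and Tnfrsf1b (-1.11). Bcl2 (1.67, adjusted p = 0.0058; chromosome 1, 106549094 to 106549402), Adamts14, a metalloprotease (1.63), Cd28 (0.73) and Grap2 (0.70) were raised. Without T4 replicate 1 each of these calls at 120 min ended, with adjusted p from 0.135 for Spry1 to 0.586 for Fyn. Without replicate 2 of T4 with PRN-694 all but that of Spry1 ended, from 0.0877 for Bcl2 to 0.437 for Fyn. Without replicate 1 of T4 with PRN-694 those of Tnfrsf1b (0.0502), Exoc2 (0.0535), Grap2 (0.0825), Slc7a1 (0.0952) and Cd28 (0.113) ended, and without T4 replicate 2 those of Grap2 (0.0549), Cd28 (0.0573), Ccl4 (0.069) and Tnfrsf1b (0.0778). With an added value of 0.1 the calls of Lclat1 (0.0731), Tnfrsf1b (0.077), Fyn (0.115), Slc7a1 (0.12), Furin (0.125), Dusp22 (0.163), Ccl4 (0.201), Exoc2 (0.25) and Il2ra (0.376) ended.

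Rel was called with the block alone at 60 min (log2 -1.42, adjusted p = 0.115, 0.00212 with the block) and 120 min (-1.08; 0.00661), as was Egr2 (-1.14, -1.17 and -0.96; 0.0244, 0.00708 and 0.0093 with the block). Egr1 (-0.54, -0.31 and 0.05) and Nr4a1 (-0.60, -0.39 and -0.60) were not called. At 30 min Tagap fell by 1.77 and Ankrd46 by 1.41 on the log2 scale (adjusted p = 0.0224 for both). Without T4 replicate 1 both calls ended (adjusted p = 1), as they did without replicate 2 of T4 with PRN-694 (0.924). Without replicate 1 of T4 with PRN-694 that of Ankrd46 ended (0.154), and with an added value of 0.1 that of Tagap (0.0872).

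The counts under T4 moved when single libraries were left out, in fits without the block. Such fits cannot part lower power from the difference between the replicate numbers, so they do not show which libraries carried the calls. Without T4 replicate 1 limma called 0 regions at 120 min, without replicate 2 of T4 with PRN-694 it called 3, without replicate 1 of T4 with PRN-694 241, and without T4 replicate 2 690 (427 higher and 263 lower). At 30 min the count was 0 without T4 replicate 1 or replicate 2 of T4 with PRN-694, and 22 without T4 replicate 2. A count of 10 was made at 60 min without replicate 1 of T4 with PRN-694. With the block the counts were 89 at 30 min and 3577 at 120 min. An added value of 0.1 gave 1 region at 30 min and 147 higher and 61 lower at 120 min, and quantile normalization 1498 regions at 120 min.

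Camera called the list of activation transcription factors, toward lower values with the inhibitor under T4, although limma called few of its regions or none. At 120 min it had 1 higher and 12 lower of 546 regions (2 and 23 adjusted over the list alone; camera adjusted p = 4.15e-05, adjusted p = 0.533 with an estimated correlation), and at 30 and 60 min 0 regions were called by limma (4 and 9 lower adjusted over the list alone; camera adjusted p = 2.20e-06 and 2.60e-06). Cytokines had 0 higher and 7 lower at 120 min (5 and 29 adjusted over the list alone; 4.85e-05; 0.607 with an estimated correlation), the NF-kB list 1 higher and 8 lower (5 and 26 adjusted over the list alone; 2.80e-04) and growth genes 1 higher and 9 lower (4 and 11 adjusted over the list alone; 0.00381). Camera called receptors toward lower values at 30 min (0.02) and 60 min (0.006), and CD4 T cell markers at 30 min (0.0478, 0.0836 with regions within 10 kb). None of these calls held with an estimated correlation. The naive list was not called at 120 min (0.742).

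The regions moved by the inhibitor under T4 were compared with those moved by N4, a comparison that shares no library. Of the 486 regions lowered by the inhibitor at 120 min, 474 were higher with N4 than in unstimulated cells (119.8 expected by chance) and 0 were lower. Of the 340 regions raised, 330 were lower with N4 (64.7 expected) and 2 were higher. With the block, 1795 of 1908 lowered regions were higher with N4 (523 expected) and 7 lower, and 1538 of 1669 raised regions were lower (381 expected) and 12 higher.

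Under N4, the same comparison asked what the inhibitor changed under a strong stimulus. Few regions were called in the fit without the replicate block, and more with it (934, 2062 and 306 at 30, 60 and 120 min). Without the block they were 5 higher and 20 lower with the inhibitor at 30 min, 10 and 40 at 60 min, and 1 and 28 at 120 min. Among those lowered at 30 min were regions in Bach2, a repressor of effector genes (-1.74, SE 0.306, adjusted p = 0.0289; chromosome 4, 32378540 to 32378786), Il6st, a cytokine receptor chain (-1.67, adjusted p = 0.0276), Adgrg1 (-1.55) and Abtb2 (-1.54). Raised at 30 min were regions in Vwf, which encodes von Willebrand factor (adjusted p = 0.0458), Srgap1 (1.05) and Fosb, an AP-1 subunit (0.93), and 2 regions with none of the genes within 50 kb, on chromosome 13 (1.33; 44065773 to 44066089) and chromosome 15 (1.10; 62092733 to 62093031). At 60 min regions in Pik3cd, a lymphocyte lipid kinase (-1.65), Phldb1 (-1.50) and Arid1a, a chromatin remodeller (-1.44, adjusted p = 0.0154), fell and a region near Mmp15, a metalloprotease (1.36), rose. At 120 min a region 39808 bp outside the gene of Tob1, an inhibitor of proliferation, fell by 1.28 on the log2 scale (adjusted p = 0.0314), and another in Sptbn1 rose by 1.04. Each of the calls under N4 ended without at least 1 of the 4 libraries. At 30 min those of all 7 genes ended without replicate 1 of N4 with PRN-694 (adjusted p = 0.0985 for Fosb to 0.138 for Il6st) and without N4 replicate 2 (0.233 for Bach2 to 0.308 for Srgap1). All but Fosb ended without N4 replicate 1 (0.0788 for Srgap1 to 0.391 for Bach2), and all but Il6st without replicate 2 of N4 with PRN-694 (0.23 for Fosb to 0.651 for Vwf). The region on chromosome 13 ended without N4 replicate 1 (0.391), N4 replicate 2 (0.195) and replicate 2 of N4 with PRN-694 (0.651). That on chromosome 15 ended without N4 replicates 1 and 2 (0.0847 and 0.442) or replicates 1 and 2 of N4 with PRN-694 (0.180 and 0.343), and under median-of-ratios scaling (0.0553). At 60 min the calls ended without replicate 1 of N4 with PRN-694 (0.135 for Arid1a to 0.244 for Phldb1), N4 replicate 1 (0.142 for Arid1a to 0.299 for Mmp15) and N4 replicate 2 (0.169 for Mmp15 to 0.289 for Phldb1). At 120 min Sptbn1 and Tob1 ended without replicate 1 of N4 with PRN-694 (0.249 and 0.435) and N4 replicate 1 (0.405 and 0.485), and Tob1 without N4 replicate 2 (0.0571). With an added value of 0.1 the calls of Abtb2 (0.0561), Adgrg1, Vwf and the region on chromosome 15 (0.0616), Bach2 (0.149), Pik3cd and Mmp15 (0.0874), Phldb1 (0.279), and Sptbn1 and Tob1 (0.0684) ended.

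Under N4 the regions at Egr1 (-0.11, 0.60 and -0.03), Nr4a1 (-0.00, 0.14 and -0.22), Il2ra (-0.32 at 120 min) and Tcf7 (0.07 at 120 min) were not called. A region near Kras, a GTPase upstream of ERK, was called with the block alone (-1.63, -1.59 and -1.29; adjusted p = 0.00189, 0.00323 and 0.0299 with the block).

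The counts under N4 also moved with single libraries. At 30 min they were 16 and 1 without replicates 1 and 2 of N4 with PRN-694, and 1 (higher) and 0 without N4 replicates 1 and 2. At 60 min they were 0 and 295 without replicates 1 and 2 of N4 with PRN-694, and 1 (higher) and 0 without N4 replicates 1 and 2. At 120 min they were 2 and 276 without replicates 1 and 2 of N4 with PRN-694, and 0 and 5 without N4 replicates 1 and 2. With the block they were 934, 2062 and 306. An added value of 0.1 gave 6, 4 (3 higher and 1 lower) and 0, total scaling 153 at 60 min, and quantile normalization 150 higher and 192 lower at 60 min and 10 and 23 at 120 min.

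Camera called the NF-kB list, toward lower values with the inhibitor under N4, at 30 min, with 0 higher and 1 lower of 382 regions (1 and 18 adjusted over the list alone; camera adjusted p = 2.60e-06, adjusted p = 0.483 with an estimated correlation), and at 60 min (0 higher and 1 lower; 0.0415), and with the block at 120 min (0.0609; 0.0407 with the block). Activation transcription factors (0.00236), receptors (0.0247) and cytokines (0.0454, 0.0977 with regions within 10 kb) were called toward lower values at 30 min. None of these calls held with an estimated correlation. Camera also called erythroid markers at 60 min, with 0 regions called by limma (0.0086, 0.228 with an estimated correlation). Of the 20 regions lowered under N4 at 30 min, 1 was higher with T4 than in unstimulated cells (0.432 expected) and 1 lower (0.458 expected). Of the 40 lowered at 60 min, 21 were higher with T4 (4.34 expected) and 0 lower. Of the 28 lowered at 120 min, 18 were higher with T4 (5.56 expected) and 1 lower. With the block, 137 of 699 lowered regions were higher with T4 at 30 min (30.3 expected) and 25 lower (34.3 expected), 716 of 1401 at 60 min (199.5 expected) and 45 lower, and 126 of 243 at 120 min (55.8 expected) and 25 lower.

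Whether the inhibitor's effect differed between the peptides was tested as an interaction. Chance alone would put a share of 0.05 of the 95623 regions at an unadjusted p under 0.05. Limma called 0 regions at 30, 60 and 120 min, with 2878, 3783 and 6474 at an unadjusted p under 0.05, below that share at 30 and 60 min. With the block it called 0, 0 and 47 (5 higher and 42 lower), and at 120 min 52 without replicate 2 of N4 with PRN-694. The interaction of the Spry1 region was 1.02 at 120 min (SE 0.39, adjusted p = 0.592) and of the Il2ra region 1.72 (adjusted p = 0.504). Activation transcription factors were called as a list at 60 min (0.0374) and 120 min (0.0326; 0.826 with an estimated correlation), pointing to a smaller loss under N4, and receptors at 60 min with the block alone (0.0862; 0.0357 with the block).

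The size of the response was read in libraries of 1 replicate number, in the 1000 regions most gained or lost with N4 in the other number. With N4 the gained regions rose by a median log2 of 2.21, 2.89 and 3.46 at 30, 60 and 120 min. N4 with PRN-694 kept 76.5% of that response at 30 min (71.6 and 81.4% in the separate replicates), 80.2% at 60 min (77.1 and 83.4%) and 86.9% at 120 min (86.1 and 87.6%). T4 reached 53.7% (41.4 and 66.1%), 68.9% (61.8 and 76.0%) and 80.6% (78.3 and 82.9%). T4 with PRN-694 reached 30.3% (22.4 and 38.3%), 44.8% (32.6 and 57.0%) and 58.3% (51.6 and 65.0%). The lost regions fell by a median log2 of -1.91, -2.25 and -2.46 with N4. N4 with PRN-694 kept 86.5% of that loss at 30 min (85.6 and 87.4% in the separate replicates), 88.0% at 60 min (86.4 and 89.6%) and 97.9% at 120 min (93.4 and 102.3%, so in 1 replicate none of it was missing). T4 reached 50.5% (44.1 and 56.8%), 63.0% (56.6 and 69.4%) and 80.7% (72.3 and 89.2%), and T4 with PRN-694 36.2% (28.7 and 43.7%), 45.9% (37.7 and 54.2%) and 59.3% (50.8 and 67.8%). In both replicate numbers the order of gained regions was N4, N4 with PRN-694, T4 and T4 with PRN-694 at each time. The regions were chosen by N4, so the place of N4 as first is partly set by that choice. No set was chosen by T4, so responses in other regions are not covered. These shares are values of 2 readings without a test.

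**Figure D4:**
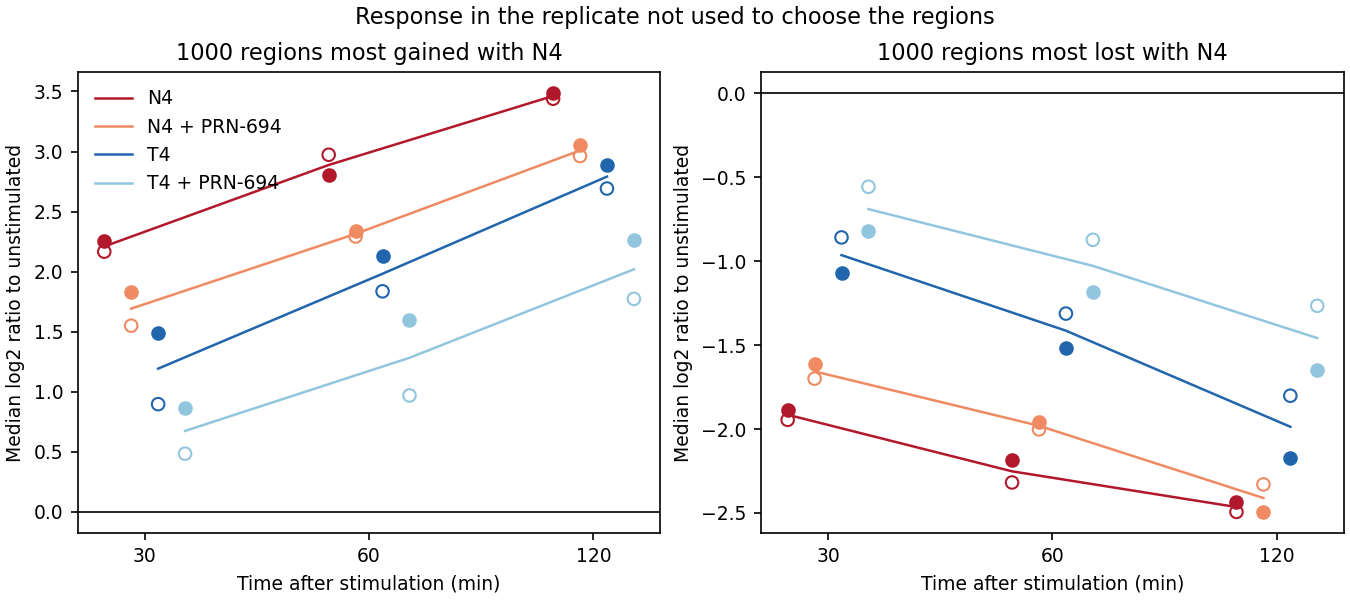
Median log2 ratio to unstimulated cells (y axis) of the 1000 regions most gained (left) or lost (right) with N4, at 30, 60 and 120 min, read in the replicate not used to choose them (points, replicates; lines, means of 2). T4 with PRN-694 reached 58.3% of the N4 gain at 120 min and N4 with PRN-694 reached 86.9%.

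Regions near gene ends were scarce among called regions. At 60 min 1954 of the 19612 regions higher with N4 (9.96%) and 12.5% of the lower ones lay within 1 kb of an end of a gene, against 26.7% of regions not called. With T4 at 120 min the shares were 11.1% of higher and 10.5% of lower regions, against 26.4%. For N4 against T4 at 30 min they were 7.32 and 5.37%, against 21.7%, and for the inhibitor under T4 at 120 min 6.18 and 10.3%, against 21.1%. These differences passed two-sided Fisher's exact tests with regions, not libraries, as units (largest adjusted p = 5.3e-10 among those given). For regions higher with T4 and PRN-694 at 30 min the share was 19.2%, against 21.0% (adjusted p = 0.578). Shares were not called different for regions lower over 60 min in culture (adjusted p = 0.326) or lowered by the inhibitor under N4 at 120 min (0.106).

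Itk and Txk, which encode the kinases that PRN-694 targets, had 27 and 12 regions. With N4 at 120 min, 10 Itk regions were higher and 12 lower, and 3 Txk regions higher and 4 lower. With T4 at 120 min, 5 Itk regions were higher and 11 lower, and 3 Txk regions higher and 4 lower. At the end of Itk (chromosome 11, 46389433 to 46389692) coverage was 75.4 ± 0.84 (SD, n = 2) in unstimulated cells, 54.9 ± 0.876 with N4, 55.6 ± 2.32 with N4 and PRN-694, 62.1 ± 6.27 with T4 and 72.5 ± 3.04 with T4 and PRN-694 at 120 min. At the end of Txk (chromosome 5, 72752700 to 72752936) it was 109.9 ± 0.664, 83.2 ± 4.46, 84.5 ± 9.53, 83.1 ± 3.14 and 88.8 ± 5.5. The inhibitor changed no called region of Itk or Txk in limma under either peptide; the lowest adjusted p was 0.0549, for Itk under T4 at 120 min.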

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

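The comparisons of 120 with 30 min and the tests of sex make-up, library depth, mitochondrial share and the held-out loss at 30 min were chosen only after the results were seen. The response to stimulation differed between times by a test of the difference itself. The N4 effect, each time net of unstimulated cells, differed between 120 and 30 min in 7687 regions (5892 with the larger value at 120 min and 1795 with the smaller). That count was 4252 without N4 at 120 min replicate 1, 4315 without N4 at 30 min replicate 2, 5010 and 4854 without unstimulated replicates 1 and 2 at 120 min, and 4892 and 4414 without unstimulated replicates 1 and 2 at 30 min. The T4 effect differed in 9652 regions (6874 and 2778). That count was 4715 without T4 at 120 min replicate 1, 6112 without T4 at 30 min replicate 2, 6234 and 6040 without unstimulated replicates 1 and 2 at 30 min, and 6345 without unstimulated replicate 2 at 120 min. The effect of PRN-694 under T4 differed in 1 region, inside Plagl2, a zinc finger factor gene (mm10 chromosome 2, 153237987 to 153238194; log2 difference -2.55, adjusted p = 0.0273). It was listed after its value was seen, and leaving out any of the 8 libraries gave 0 regions, except for replicate 2 of T4 with PRN-694 at 120 min, which gave 1. Camera called growth genes for this difference, toward lower values (0 regions called by limma; camera adjusted p = 0.0346, 0.305 with an estimated correlation). Under N4 limma called 0 regions for this difference.

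PRN-694 changed few regions under N4 at 120 min, 29 against 826 under T4 (306 against 3577 with the replicate block). At the other times the order was the other way, with 25 against 2 at 30 min and 50 against 0 at 60 min (934 against 89 and 2062 against 677 with the replicate block). The 826 became 0 without T4 replicate 1 and 3 without replicate 2 of T4 with PRN-694. The library of N4 with PRN-694 at 120 min replicate 1 was the shallowest. Without it limma called 2 regions, and without replicate 2 it called 276. The bound set beforehand, a count that does not rise without the shallow library, decides nothing here, because a lone library lowers the power by itself and the 276 rest on the shallow library alone in its group. Its depth stays open as a reason for the low count, and so does a smaller effect of the inhibitor under N4. In held-out regions the log2 response lost with PRN-694 was 0.431 and 0.477 in the replicates under N4 and 0.625 and 0.919 under T4, larger under T4 by 0.194 and 0.442, which is consistent with it at that time. At 60 min the loss was larger under T4 by 0.0665 in replicate 1 and 0.187 in replicate 2, the opposite order to the counts at that time. At 30 min the difference was 0.206 in replicate 1 and -0.204 in replicate 2, so the replicates did not agree at that time. The interaction of inhibitor and peptide called 0 regions in limma at 120 min, 47 with the replicate block and 52 without replicate 2 of N4 with PRN-694, so a difference between the peptides is a hypothesis.

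Cells of another type from the presenting splenocytes could add their marker regions to stimulated libraries, although the sort for CD45.2+ CD8a+ cells would remove them. Under N4 at 120 min, 47 of 79 B cell marker regions lay above 0, with a median of 0.19. That median stood at percentile 80.6 of 10000 random sets matched in size and level (random median 0.10, range of the central 95% from -0.10 to 0.32). With T4 it stood at percentile 48.1, and myeloid and dendritic markers stood at 38.7 under N4. Of the named B cell markers H2-Aa rose and Cd79a fell, from a coverage of 25.5 ± 0.768 to 3.19 ± 1.84. None of the 23 B cell genes is on another list, and a small share of such cells cannot be told apart from none, because the median lies inside the random range and activated T cells may open some of these regions.

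The replicate numbers parted the libraries in every group, with 31545 of 95623 regions different between numbers in the blocked fit. The mice behind the 2 numbers differed in sex make-up, which is a candidate explanation of the split. Over 15 regions of chromosome Y (259097 to 1286708) the mean coverage was 8.12 in replicate 2 (7.02 to 9.27 over libraries) and listed at 0 in all 16 libraries of replicate 1. The ratio of X to autosomal coverage was 0.768 ± 0.0322 (SD, 16 libraries) in replicate 1 and 0.653 ± 0.0118 in replicate 2. Library depth did not follow the split, since replicate 2 was deeper in 8 of 16 groups. The mitochondrial share of coverage was higher in replicate 1 in 15 of 16 groups, so the numbers differ in a sign of library quality as well. Regions on X and Y alone did not account for the split, as differences on the autosomes still correlated between groups at a median r of 0.219 (lowest 0.0982), so sex and any difference of day or handling stay open together for the autosomes.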

How the results depend on the processing

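Quantile normalization, the replicate block with an estimated correlation, and all settings of the comparisons of 120 with 30 min and of N4 with PRN-694 against T4 were chosen only after the data were seen. The other settings given here were planned. None of 1669 calls of named regions reversed under any setting tried. The larger side of the called regions did turn in some counts, which the report gives. Of those 1669 calls, 14 ended under median-of-ratios scaling, 42 under total scaling, 0 without the filter, 129 with an added value of 0.1, 0 with the replicate block and 77 under quantile normalization, and 1104 of 6676 trials that left out 1 library ended a call; the cause was not tested. The block added 11 calls of lists and ended 1. Those that the report leaves out are, with N4 and PRN-694 at 120 min, the NF-kB list (adjusted p = 0.0674, 0.0372 with the block) and MAPK feedback (0.0664, 0.0407 with the block), and with T4 and PRN-694 the NF-kB list (0.0674, 0.0407 with the block) and growth genes (0.0505, 0.0401 with the block) at 60 min and receptors at 120 min (0.055, 0.0227 with the block). It changed no other call of a list, ended no call of a named region, and ended few calls among all regions (33448 of 33459 held for T4 at 120 min). The median log2 change over all regions moved by up to 0.125 under quantile normalization and by less than 0.1 under the other scalings. With the block the counts, in the order of 30, 60 and 120 min, were 86, 772 and 3105 over time in culture, 8847 for T4 at 30 min, 2030 and 12409 for T4 with PRN-694 at 30 and 60 min, 9966, 8377 and 2054 for N4 against T4, 934, 2062 and 306 for the inhibitor under N4, 89, 677 and 3577 under T4, and 47 for the interaction at 120 min. Between 120 and 30 min they were 13592 for N4, 16133 for T4, 2 for the inhibitor under T4 and 4 under N4, and for N4 with PRN-694 against T4 1483, 1023 and 230. An added value of 0.1 gave 97 over 60 min in culture, 1668 and 168 for N4 against T4 at 60 and 120 min, 6, 4 and 0 for the inhibitor under N4, 1 and 208 under T4 at 30 and 120 min, 3981 for N4 and 0 for the inhibitor under T4 between 120 and 30 min, and 61 for N4 with PRN-694 against T4 at 120 min. Total scaling gave 153 for the inhibitor under N4 and 2 under T4 at 60 min, and 93 (20 higher and 73 lower) and 82 for N4 with PRN-694 against T4 at 30 and 60 min. Median-of-ratios scaling gave 23 over 60 min in culture. Quantile normalization gave 262 over 120 min in culture, 838 for N4 against T4 at 120 min, 342 for the inhibitor under N4 and 6 under T4 at 60 min, 1498 under T4 at 120 min, 111 and 40 for N4 with PRN-694 against T4 at 30 and 120 min, and 4832 higher and 2542 lower for N4 between 120 and 30 min. The 94 calls of lists became 0 with an estimated correlation and 0 with the block and an estimated correlation, while 93 held with the block and 84 with regions within 10 kb. With the top 300 regions N4 with PRN-694 kept 91.3% of the loss at 60 min and 91.2% of the gain at 120 min; the cause was not tested. Leaving out each library in turn gave 0 to 1, 0 to 7 and 36 to 150 regions over time in culture, 15387 to 16997, 26246 to 28279 and 33972 to 35999 for N4, 566 to 4540, 9019 to 14476 and 23719 to 28169 for T4, 8726 to 10297, 18473 to 26208 and 30781 to 35253 for N4 with PRN-694, and 30 to 490, 1006 to 6864 and 10495 to 19104 for T4 with PRN-694. It gave 546 to 4066, 202 to 2445 and 27 to 114 for N4 against T4, 0 to 16, 0 to 295 and 0 to 276 for the inhibitor under N4, 0 to 22, 0 to 10 and 0 to 690 under T4, and 0 to 0, 0 to 0 and 0 to 52 for the interaction. Between 120 and 30 min it gave 4252 to 6105 for N4, 4715 to 8552 for T4, 0 to 1 for the inhibitor under T4 and 0 to 5 under N4, and for N4 with PRN-694 against T4 10 to 68, 0 to 669 and 0 to 260. Fewer libraries lower the power of each of these. They also leave a group with 1 replicate number against groups with both, in fits without the block. Lower power and the difference between the numbers cannot be told apart here, and lower power alone would not raise a count. Otherwise the cause was not tested. The DESeq2 alternative and the window for motifs were not run, since the values are no counts and no sequence was at hand.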

Other observations

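The comparisons here were all chosen after the data were seen, with no leaving out of libraries for single regions. Regions with an early and passing response to N4 numbered 254: they were higher at 30 min and lower by 120 min than at 30 min, each net of unstimulated cells. The largest fall was at Egr3 (mm10 chromosome 14, 70084930 to 70085560), from log2 5.02 at 30 min to 1.05 at 120 min (difference -3.96, adjusted p = 3.06e-06). A region at Jarid2, a chromatin regulator, went from 2.48 to -0.80 (difference -3.29), a region at Fos, an AP-1 subunit, from 3.56 to 1.47 (-2.10, adjusted p = 0.00938), and a region at Tnfsf11, a cytokine gene, from 1.05 to -1.28. Regions with a late response numbered 5571. Mtap, a gene of methionine salvage (chromosome 4, 89149320 to 89149573), went from 0.07 at 30 min to 4.80 at 120 min (adjusted p of the difference = 4.33e-06), Gtdc1 from -0.04 to 4.55, Malt1, an NF-kB protease, from -0.57 to 3.31, and Pou2f2, a lymphocyte factor, from 0.72 to 4.42. Between 120 and 30 min growth genes were higher as a list with N4 (64 regions higher and 6 lower; adjusted p = 0.00221, 0.119 with an estimated correlation) and with T4 (64 and 7; 0.0019, 0.119 with an estimated correlation), as were cytokines (33 and 5 with N4, adjusted p = 0.00367, 0.987 with an estimated correlation; 43 and 7 with T4, 7.58e-04, 0.946 with an estimated correlation).

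N4 with PRN-694 was set against T4 without it. The pair had kept similar shares of the N4 gain at 120 min (86.9 and 80.6%), but less similar ones at 30 min (76.5 and 53.7%) and 60 min (80.2 and 68.9%). N4 with PRN-694 had kept more of the N4 loss at each time (86.5 against 50.5%, 88.0 against 63.0% and 97.9 against 80.7%). The pair is therefore not matched in the size of the response, and a larger loss by itself would give more lower regions. Regions that differed were mostly lower with N4 and PRN-694: 235 against 27 higher at 30 min, 130 against 7 at 60 min and 21 against 0 at 120 min. Of these lower regions 229, 128 and 21 had been lowered by N4 (29.1, 21.0 and 4.00 expected by chance, with libraries of unstimulated cells and N4 that the comparison does not use). Wwox was lower by log2 -1.74 at 30 min (SE 0.204, adjusted p = 1.9e-04), Klhl6 by -1.87 and Mmp25, a metalloprotease, by -1.22. Tcf7 was lower by -1.20 at 60 min (adjusted p = 7.49e-04), and Pecam1, an adhesion receptor, by -1.37. Higher at 30 min were Dlgap4, a scaffold gene (1.64, adjusted p = 0.00446), and Smad3, a TGF-beta mediator (1.39). The naive list was lower at 30 min (18 of 890 regions; adjusted p = 4.03e-05, 0.305 with an estimated correlation), at 60 min (10 regions; 6.62e-05, 0.305 with an estimated correlation) and 120 min (1 region; 0.0379, 0.946 with an estimated correlation). Camera also called erythroid markers at 60 min, with 0 of 29 regions called by limma (adjusted p = 0.00984, 0.119 with an estimated correlation). Without a library the count at 30 min was 68 and 10 (replicates 1 and 2 of N4 with PRN-694) and 61 and 19 (T4 replicates 1 and 2). At 60 min it was 8 and 669, and 57 and 0, and at 120 min 1 and 260, and 5 and 0, in the same order. With the block the counts were 1483 (443 higher and 1040 lower), 1023 (150 and 873) and 230 (19 and 211).

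Between the replicate numbers, CD4 T cell marker regions were lower in replicate 2 (53 lower and 4 higher of 141; adjusted p = 6.51e-06, 0.0393 with an estimated correlation). So were 5 other lists: cytokines (80 lower and 6 higher of 252; 1.79e-04, 0.293 with an estimated correlation), activation receptors (139 and 25 of 479; 1.79e-04, 0.293 with an estimated correlation), and activation transcription factors (154 and 48 of 546), the NF-kB list (104 and 26 of 382) and T cell receptor signalling components (294 and 87 of 1120), with 0.00768 for these 3 (0.431, 0.293 and 0.401 with an estimated correlation). Of the 12 CD4 marker genes 5 are on another list. The lists were tested with their regions on X kept. Of the 1001 regions on X that differed between the numbers 114 were higher in replicate 2, against 14636 of 31545 over all regions. The difference in sex can therefore enter any list that holds regions on X.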
